A study of Homo sapiens with 15 samples.

How the data were processed

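RNA of BeWo choriocarcinoma cells (control, overexpressing STOX1A or overexpressing STOX1B, each under DMSO or forskolin) was hybridised to 15 Clariom S arrays, 1 per sample, per the labels' protocols. The submitters' processing notes name the Transcriptome Analysis Console, and its version, settings and normalization method are not given in the sources used here. The deposited values are log2 signals, per the range of the file, from 2.2147 to 19.9277. That upper end lies above the log2 of the brightest signal that scanners of this kind usually record, so the scale appears to have been stretched during summarisation, and differences are given in deposited log2 units, not as folds of RNA. The arrays' quartiles differed, so the deposited log2 values had not been quantile-normalized over all rows.

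The deposited table holds 24351 rows. The 3458 control or unmapped rows were left out of the tests, and of the 20893 transcript rows 17705 had 1 gene symbol in the platform annotation, 0 had several and 3188 were unnamed here. The 17705 rows stand for 17687 symbols, which an update through Entrez identifiers left unchanged. For 17 symbols there is more than 1 row, and each row was tested on its own. Rows of near-identical genes (the CGB genes, pregnancy-specific glycoproteins, metallothioneins, histones, FAM72, CKMT1A and ANXA8L1) cannot be assigned to 1 copy with certainty. No pair of arrays held identical values. Background was set on each array as the 95th percentile of its 612 negative-control rows (5.60 to 6.71). Where all arrays of the lower group were at or below it, a difference is printed as "at least" the mean of the brighter group minus the mean, over the arrays of the dim group, of the higher of background and the row's own value. No size is given where both groups were below background. A row within 0.3 log2 units of the brightest named row on all arrays of a group was treated as having reached the top of the scale, and the difference is likewise printed as "at least". A difference of forskolin effects has a bound, computed in the same way, only where no group at background adds to it and no group at the top takes from it, and otherwise its adjusted p is printed without a size or direction.

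Groups came from the cell line, construct and treatment in the labels. All 15 arrays entered 1 limma fit of 6 group means (lmFit and eBayes, 9 residual degrees of freedom, prior 8.83), in which the groups share the estimate of spread, and 12 contrasts were taken: forskolin against DMSO in each of the 3 lines, each STOX1 line against control under each treatment, STOX1A against STOX1B under each treatment, and the 3 differences of forskolin effects. Adjusted p are limma's, corrected by Benjamini-Hochberg over 17705 rows within a contrast, two-sided, with a threshold of 0.05. The named genes follow a rule fixed before the data were examined: STOX1 throughout and CGA, CGB3, ERVW-1, ERVFRD-1, GCM1, CYP19A1, HSD11B2, CDH1, GJA1 and CREM for forskolin. It adds the 10 highest and 10 lowest called rows whose groups do not overlap in each forskolin or against-control contrast, and 5 and 5 called rows in the others, and up to 4 called members of each called list, with the least changed left out where space required.

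The 34 gene lists (1031 genes, of which 903 were measured) were also fixed beforehand: trophoblast fusion, placental hormones, pregnancy-specific glycoproteins, steroid synthesis, villous cytotrophoblast and stem state, extravillous trophoblast, preeclampsia placenta, cAMP and CREB targets, imprinted genes, mitosis, DNA replication, histones, p53 targets, ribosomal proteins, respiratory chain, hypoxia and glycolysis, antioxidant genes, unfolded protein response, heat shock, ATF4 targets, interferon response, NF-kB and cytokines, TGF-beta and BMP targets, Wnt pathway, matrix, adhesion, tight junction, epithelial-mesenchymal, cholesterol synthesis, immediate early genes (a sign of stress or RNA handling), and markers of endothelium, fibroblasts, blood and macrophages, and neurons and glia as other cell types. They overlap in part. Each was tested with camera at a preset correlation of 0.01, corrected over the 34 lists within a contrast, giving 408 tests of which 153 passed, and again with a correlation estimated from the data, with which 45 passed. No threshold was adjusted over the 12 contrasts.

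The fit was tested on 17705 simulated rows, 200 of them changed. Their spread was that of the real rows, equal in all groups, unlike the array weights (0.48 to 2.14). Of changes of 2 log2 units the fit recovered 92% and 100% for forskolin in control and STOX1A cells. Of changes of 1 unit it recovered 18% and 44%, with 6 false calls each. Against control under DMSO, STOX1A and STOX1B had 98% and 96% (2 units) and 15% each (1 unit), with 5 and 3 false calls.

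Alternatives were quantile normalization, subtraction of array medians, leaving out the 5902 dimmest rows, a trended and robust prior, array weights, only the groups of a comparison, the replicate number as a block, 1 value per symbol, and leaving out each array in turn. For the lists, fry and the estimated correlation were added. A pseudocount, planned for linear values, did not apply to log2 values. Leaving out 10818 rows not above background in any whole group, leaving out 101 rows in blocks of neighbouring genes, and giving each STOX1 line 1 of the 2 control arrays, were alternatives chosen after seeing the data. The order of neighbouring genes came from the RefSeq annotation of GRCh38.p14, used for order only, since the build behind the array annotation is not given in the sources used here. R 4.3.3, limma 3.58.1, Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 were used.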

Results

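Gene expression was profiled on 15 Clariom S arrays of BeWo cells, a human choriocarcinoma line whose cells stay mononucleated in culture and fuse into a syncytium when cyclic AMP rises. The cells were controls or overexpressed 1 of the 2 isoforms of STOX1 (STOX1A or STOX1B), a winged-helix transcription factor studied in preeclampsia, and were kept under selection with Geneticin. Part of the cells received forskolin, an activator of adenylate cyclase, at 24 µM for 3 days, and the remainder is labelled DMSO. Control cells had 2 arrays under DMSO and 2 under forskolin, STOX1A cells had 3 and 3, and STOX1B cells had 2 and 3. The design asks what forskolin changed in each line, how each STOX1 line differed from control under either treatment, how the isoforms differed, and whether the forskolin response itself differed. Array medians lay between 4.54 and 4.68 (log2 signal). Between 26.0% and 39.6% of the 17705 named rows exceeded the background of an array. The 3 STOX1A arrays under forskolin had 26.5%, 26.0% and 27.9%, and the 2 control arrays under forskolin had 39.6% and 37.1%. The number of arrays limits the precision. The labels do not say whether the arrays of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

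All changes below are differences of deposited log2 signals with their standard error from the limma fit, and group levels are means ± SD. A gene counts as called at a limma adjusted p under 0.05. Where a group lay at or below background or near the top of the scale on all its arrays, the change is given as "at least". A difference of forskolin effects is given in the same way where such groups allow a bound, and with its adjusted p alone, without size or direction, where they allow none. Genes were picked by fitted change, which gives no rank where a change is only bounded, and means of lists and counts of called rows use fitted values that include rows at background. Counts of list members are rows, and the 36 rows of the ATF4 target list and the 30 of the cAMP and CREB target list stand for 35 and 29 genes, since CBS and PRKAR1A have 2 rows each. A gene list counts as called by camera with a preset correlation. A second adjusted p, with a correlation estimated from the data, is given for each list that loses the call with it. The row of STOX1 lay below background on all 15 arrays. Its mean was 3.63 ± 0.50 (SD, n = 2) in control cells under DMSO, 3.95 ± 0.07 (n = 3) in STOX1A cells and 4.37 ± 0.27 (n = 2) in STOX1B cells. Under forskolin the means were 3.73 ± 0.35 (n = 2), 4.53 ± 0.62 (n = 3) and 4.51 ± 0.15 (n = 3). None of the 12 comparisons called it, with the lowest adjusted p at 0.10 for STOX1A against control under forskolin. Which part of the transcript the probes cover relative to the expression constructs is not given in the sources used here, so the row does not check the labels.

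Forskolin in control cells raised placental hormone genes and lowered tight junction and interferon response genes. CGA, the common alpha subunit of chorionic gonadotropin, went from 13.60 ± 0.05 to 19.86 ± 0.01 (n = 2 each), a rise of at least 6.26 because it reached the top of the scale. The beta subunit rows rose too, CGB8 by 6.60 ± 0.55, CGB3 by at least 5.50 and CGB5 by at least 5.76. MMP2, a gelatinase, rose by at least 10.08 to the top of the scale, the placental serine protease gene HTRA4 by at least 7.71, and the nuclear receptor gene NR4A3 by at least 5.0. GPR32 (7.66 ± 0.60), HEY1, a Notch target (5.81 ± 0.34), and SAT1, which acetylates polyamines (5.67 ± 0.47), were higher too, all with adjusted p at or below 4.6e-06. The interferon-induced gene IFI6 changed by -8.36 ± 0.55, OLR1, a receptor for oxidised lipoprotein, by -4.44 ± 0.58, CRIM1 by -4.20 ± 0.30 and CEACAM1 by -4.05 ± 0.38. SLC7A6 (-4.03 ± 0.40), the desaturase gene FADS2 (-3.88 ± 0.41) and EPCAM (-3.75 ± 0.49) were also lower, with adjusted p at or below 8.9e-05. BCAT1, ENC1 and ARL15 fell to background, by at least 3.42, 3.02 and 2.81.

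Of the genes fixed in advance, GCM1, a transcription factor of trophoblast fusion, rose by 3.77 ± 0.63 and ERVW-1, which encodes syncytin-1, by 1.85 ± 0.36 in these control cells. E-cadherin (CDH1) changed by -2.64 ± 0.32. Syncytin-2 (ERVFRD-1, 1.67 ± 0.58, adjusted p = 0.16) and aromatase (CYP19A1, 1.63 ± 0.82, adjusted p = 0.50) did not pass the test, and HSD11B2 and GJA1 lay below background in both conditions. CREM was unnamed among the rows. The ERVW-1 call was lost without control DMSO replicate 1 (adjusted p = 0.051) and without control forskolin replicate 1 (adjusted p = 0.059).

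Placental hormone genes were higher with forskolin in control cells (13 of 27 higher, 14 higher adjusted over the list alone, mean 2.22, camera adjusted p = 2.5e-22). Pregnancy-specific glycoproteins were too (8 of 10 higher, 9 higher adjusted over the list alone, mean 2.67), among them PSG9 by at least 2.73 and PSG5 by at least 2.78. The list of genes reported as altered in preeclamptic placentas was called as higher (12 of 32 higher, 15 higher adjusted over the list alone), with TREM1 at least 3.12 and PGF 4.20 ± 0.51. Extravillous trophoblast markers (7 of 25 higher and 1 lower, 8 higher and 1 lower adjusted over the list alone) and immediate early genes (7 of 23 higher, 12 higher adjusted over the list alone) were called as higher. So were cAMP and CREB targets (9 of 30 higher, 10 higher adjusted over the list alone), with PDE4D at 4.19 ± 0.52. Hypoxia and glycolysis genes (8 of 37 higher, 10 higher adjusted over the list alone) included DDIT4 at 4.96 ± 0.37 and ADM at 4.54 ± 0.36. ATF4 targets (9 of 36 higher and 1 lower, 16 higher and 1 lower adjusted over the list alone) and trophoblast fusion genes (5 of 24 higher and 1 lower, 8 higher and 1 lower adjusted over the list alone) were higher, the latter with SDC1 at 4.15 ± 0.59 but TJP1 at -2.27 ± 0.50. Epithelial-mesenchymal genes were called as higher through MMP2, TGFB1 and SNAI1 (3 of 25 higher, the same adjusted over the list alone, mean 0.61).

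Tight junction genes were lower in control cells (5 of 18 lower and 1 higher, 6 lower and 1 higher adjusted over the list alone), with PATJ at -2.64 ± 0.47, and so were cytotrophoblast and stem-state genes (8 of 26 lower, 9 lower adjusted over the list alone). Interferon response genes were lower (5 of 43 lower, 9 lower and 1 higher adjusted over the list alone), IFI6 among them and IFITM3 at -3.31 ± 0.59. All the lists described so far kept their call with an estimated correlation (adjusted p at most 0.043). The next lists of forskolin in control cells lost it with an estimated correlation. The steroid synthesis list (adjusted p = 0.086, 3 of 18 higher and 1 lower, the same adjusted over the list alone) and the NF-kB and cytokine list (adjusted p = 0.061, 3 of 27 higher, the same adjusted over the list alone) were higher. So was the endothelial marker list (adjusted p = 0.18, 1 of 15 higher, the same adjusted over the list alone), where CDH5 was the member called. The unfolded protein response list (adjusted p = 0.3, 3 of 33 higher, 5 higher and 1 lower adjusted over the list alone) and the histone list (adjusted p = 0.3, 1 of 43 higher, the same adjusted over the list alone) were higher too. The DNA replication list (adjusted p = 0.29, 3 of 39 higher, 4 higher adjusted over the list alone) was also higher. The p53 target list (adjusted p = 0.057, 4 of 25 lower and 1 higher, 7 lower and 1 higher adjusted over the list alone) and the respiratory chain list (adjusted p = 0.5, 4 of 53 lower, 4 lower and 1 higher adjusted over the list alone) were lower. The ribosomal protein list (adjusted p = 0.53, 0 of 42 called, the same adjusted over the list alone) had a mean of 0.17, which turned to -0.13 with quantile normalization.

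In all, 663 rows were called in control cells, 322 higher and 341 lower. The number was 1858 with array weights, 1621 with only these 4 arrays in the fit, 359 and 380 without control DMSO replicates 1 and 3, and 388 and 362 without control forskolin replicates 1 and 2. TJP1 lost its call without control DMSO replicate 1 (adjusted p = 0.076) or 3 (adjusted p = 0.11) and without control forskolin replicate 2 (adjusted p = 0.17), SNAI1 without control DMSO replicate 3 (adjusted p = 0.14) or control forskolin replicate 2 (adjusted p = 0.13), and IFITM3 without control forskolin replicate 1 (adjusted p = 0.051).

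**Figure D1:**
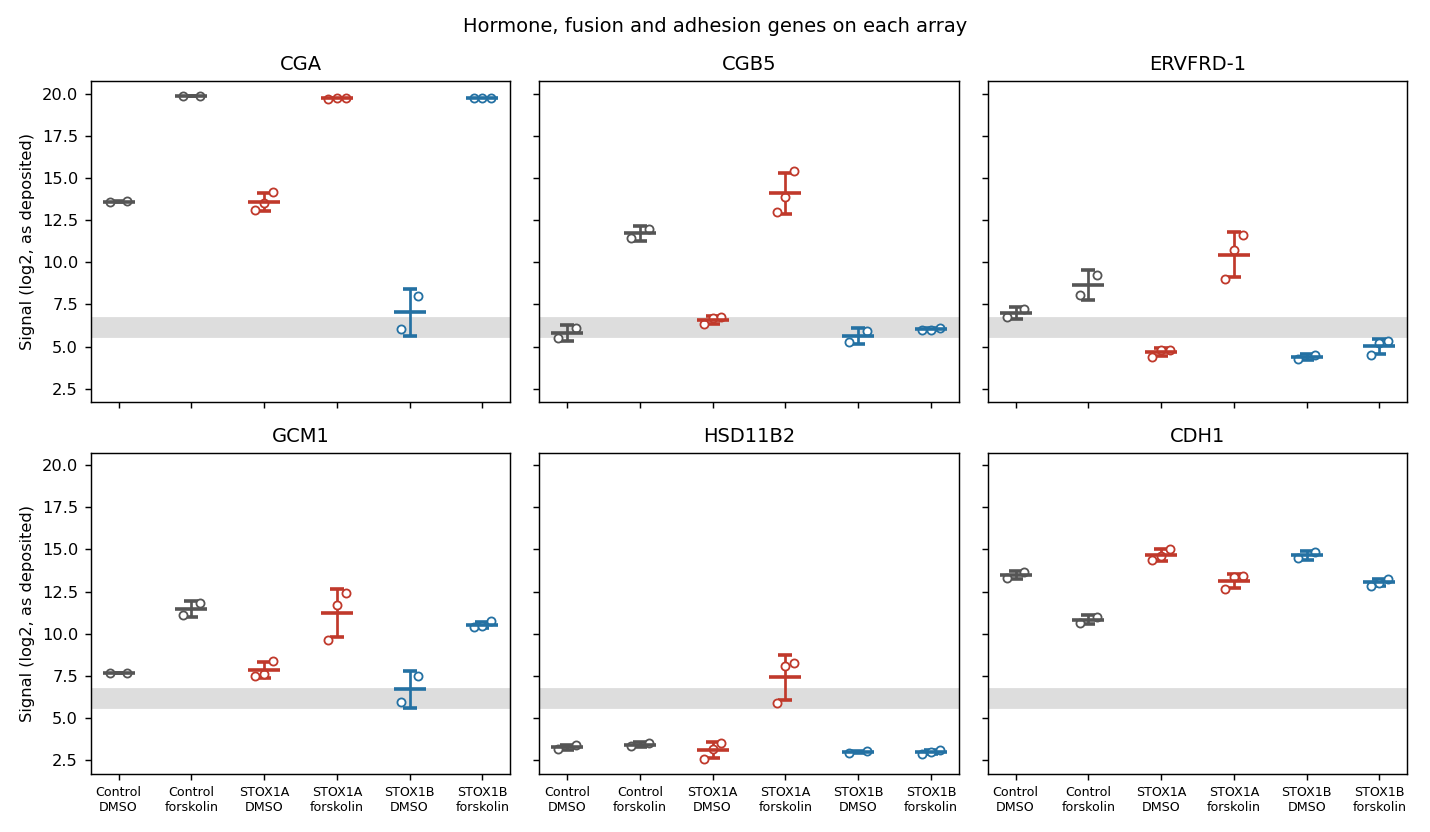
Deposited log2 signal (y axis) of 6 genes on each array (open circles) in the 6 groups (x axis), with the group mean (bar) and SD (whiskers; n = 2 or 3); the grey band spans the backgrounds of the arrays, 5.60 to 6.71. CGA reached the top of the scale in the 3 lines under forskolin, while CGB5 lay between 5.99 and 6.13 on the 3 STOX1B arrays under forskolin.

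Forskolin in STOX1A cells raised placental hormone, immediate early, unfolded protein response and trophoblast fusion genes and lowered tight junction genes. Among the 10 rows with the highest fitted change were NR4A2 (at least 6.53) and NR4A1 (at least 7.77), immediate early nuclear receptors, HTRA4 (8.92 ± 0.28), the germ-cell alkaline phosphatase gene ALPG (8.27 ± 0.26) and MFSD12 (at least 6.59). CGB8 (7.75 ± 0.45), CGB3 (7.6 ± 0.51), CGB5 (7.49 ± 0.42), the stress cytokine gene GDF15 (7.14 ± 0.41) and MMP2 (at least 7.10) were the others. CGA rose from 13.59 ± 0.52 to 19.71 ± 0.03 (n = 3 each), at least 6.12. Syncytin-2 (ERVFRD-1) rose from below background to 10.44 ± 1.34, at least 4.21, ERVW-1 by 2.52 ± 0.30 and GCM1 by 3.39 ± 0.52. HSD11B2, which inactivates cortisol, rose from background on 3 arrays to 7.41 ± 1.32, above background on 2 of 3, by at least 1.18. CDH1 changed by -1.53 ± 0.26, and CYP19A1 was not called (0.74 ± 0.67, adjusted p = 0.47). GJA1 passed the test but lay below background under both conditions. EPCAM (-6.77 ± 0.40), the death ligand gene TNFSF10 (-6.61 ± 0.51), IFI6 (-5.99 ± 0.45), HACD2 (-5.73 ± 0.31) and the fucosyltransferase gene FUT8 (-5.25 ± 0.25) were lower. FADS2 (-5.08 ± 0.34), PATJ (-5.07 ± 0.38), DCBLD2 (at least 3.72 lower), CENPF (at least 3.95 lower) and ANKRD36C (at least 3.57 lower) were lower too. The adjusted p of these 10 falls and of the 10 rises were at or below 4.0e-08.

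Immediate early genes were higher with forskolin in STOX1A cells (15 of 23 higher, the same adjusted over the list alone, mean 2.66, camera adjusted p = 4.6e-16), with DUSP1 at least 4.54 and ATF3 6.41 ± 0.24. Placental hormones were higher (13 of 27 higher, 14 higher adjusted over the list alone), as were cAMP and CREB targets (14 of 30 higher and 3 lower, 15 higher and 3 lower adjusted over the list alone). Trophoblast fusion genes (11 of 24 higher and 2 lower, the same adjusted over the list alone) included SDC1 at 6.87 ± 0.48 and the endogenous retroviral envelope genes ERVV-2 at 5.95 ± 0.45 and ERVV-1 at 5.80 ± 0.34. ATF4 targets were higher (21 of 36 higher and 4 lower, 22 higher and 4 lower adjusted over the list alone), with DDIT3, the CHOP gene, at least 4.07. The unfolded protein response was higher (23 of 33 higher and 3 lower, the same adjusted over the list alone), with HERPUD1 at 5.92 ± 0.26, and so was the preeclampsia list (13 of 32 higher, 14 higher adjusted over the list alone), with PGF at 6.55 ± 0.42. Tight junction genes were lower (8 of 18 lower and 1 higher, 8 lower and 2 higher adjusted over the list alone), with TJP1 at -4.02 ± 0.41. These lists kept the call with an estimated correlation (adjusted p at most 0.039). The tight junction list lost it when rows below background were left out (adjusted p = 0.11), an alternative chosen after seeing the data.

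Mitosis genes were lower with forskolin in STOX1A cells by camera (mean -1.62, adjusted p = 1.3e-11), with 25 of 36 called lower and 0 higher, and 27 lower and 1 higher adjusted over the list alone. With an estimated correlation this list had adjusted p = 0.058. ASPM was lower by at least 3.26, NCAPG changed by -3.86 ± 0.33 and MKI67, a proliferation marker, by -3.82 ± 0.28. Other lists of this comparison that lost the call with an estimated correlation were the histone list (adjusted p = 0.06, 20 of 43 higher, 22 higher adjusted over the list alone), with H2BC14 at 4.08 ± 0.23, and the extravillous trophoblast list (adjusted p = 0.058, 6 of 25 higher and 2 lower, 7 higher and 2 lower adjusted over the list alone). The heat shock list (adjusted p = 0.3, 7 of 20 higher and 2 lower, 8 higher and 2 lower adjusted over the list alone) lost it too, with HSPB8 at 6.89 ± 0.33 and DNAJB1 at 5.10 ± 0.34, and so did the pregnancy-specific glycoprotein list (adjusted p = 0.063, 4 of 10 higher, 7 higher adjusted over the list alone). Of the 4 glycoproteins called, 3 lay below background in both conditions. The remaining ones were higher, the NF-kB and cytokine list (adjusted p = 0.062, 5 of 27 higher and 1 lower, 4 higher and 1 lower adjusted over the list alone) and the epithelial-mesenchymal list (adjusted p = 0.14, 5 of 25 higher and 2 lower, the same adjusted over the list alone). The ribosomal protein list (adjusted p = 0.22, 15 of 42 higher, 17 higher adjusted over the list alone) was the last. In STOX1A cells 4641 rows were called, 1657 higher and 2984 lower. The higher share was 35.7% as deposited and 46.4% after quantile normalization, which called 4475. Rows above background were fewest on the STOX1A forskolin arrays.

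Forskolin in STOX1B cells raised CGA and immediate early genes, while the beta subunit row CGB3 stayed below background. CGA went from 7.04 ± 1.38 (n = 2, above background on 1 of 2 arrays) to 19.74 ± 0.01 (n = 3), at least 12.71. CGB3 (not called, adjusted p = 0.72), ERVFRD-1, CYP19A1, HSD11B2 and GJA1 lay below background in both conditions. ERVW-1 was not called (0.56 ± 0.33, adjusted p = 0.37). GCM1 rose by 3.79 ± 0.58 and CDH1 changed by -1.61 ± 0.29. NR4A3 rose by at least 7.65, HTRA4 by at least 7.88, MMP2 by at least 8.43, SAT1 by 7.44 ± 0.43 and LAIR2 by at least 6.14. The phosphatase gene DUSP1 (at least 4.82), MFSD12 (6.58 ± 0.42), HEY1 (6.56 ± 0.31) and the matricellular gene CCN1 (6.34 ± 0.46) rose as well, with adjusted p at or below 3.2e-08. IFI6 (-6.89 ± 0.50), CD24 (-5.35 ± 0.33), CEMIP2 (-5.05 ± 0.30), FSCN1, an actin bundler (-5.04 ± 0.48), CEACAM1 (-4.82 ± 0.34) and LAMA1, a laminin chain (-4.78 ± 0.46), were lower. CRYBG1, BCAT1, PLXNA2 and FERMT1 fell to background, by at least 2.14, 4.14, 1.94 and 3.02 (adjusted p of these 10 at or below 2.1e-06).

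Immediate early genes were higher with forskolin in STOX1B cells (12 of 23 higher, 13 higher adjusted over the list alone, mean 1.64, camera adjusted p = 5.6e-13), with FOS at least 2.99. The unfolded protein response (14 of 33 higher, 15 higher and 1 lower adjusted over the list alone) was higher, with MANF at 2.75 ± 0.28, and so was the preeclampsia list (13 of 32 higher, the same adjusted over the list alone). Hypoxia and glycolysis genes (16 of 37 higher and 1 lower, 18 higher and 1 lower adjusted over the list alone) included HK2 at least 3.97 higher, and ATF4 targets (15 of 36 higher and 2 lower, the same adjusted over the list alone) included CTH at least 3.52 higher. Placental hormones (6 of 27 higher, the same adjusted over the list alone) had GDF15 at 4.62 ± 0.46, and cAMP and CREB targets were higher as well (10 of 30 higher, 11 higher and 1 lower adjusted over the list alone). Extravillous markers (6 of 25 higher and 1 lower, 7 higher and 1 lower adjusted over the list alone) had ITGA5 at 4.04 ± 0.27, and trophoblast fusion genes (9 of 24 higher and 2 lower, the same adjusted over the list alone) had ERVH48-1 at 2.89 ± 0.36. Cytotrophoblast and stem-state genes were lower (10 of 26 lower, 11 lower and 1 higher adjusted over the list alone), with KRT7 at -2.95 ± 0.31 and VGLL1 at -2.81 ± 0.39, and so were interferon response genes (12 of 43 lower, 14 lower adjusted over the list alone). These calls held with an estimated correlation (adjusted p at most 0.028). Calls lost with an estimated correlation were the DNA replication list (adjusted p = 0.39, 9 of 39 lower and 1 higher, 10 lower and 1 higher adjusted over the list alone), lower, and the epithelial-mesenchymal list (adjusted p = 0.063, 3 of 25 higher and 1 lower, the same adjusted over the list alone), higher. The ribosomal protein list (adjusted p = 0.51, 1 of 42 higher, 0 adjusted over the list alone) had a mean of 0.28, and -0.17 with quantile normalization. The fit called 1913 rows, 797 higher and 1116 lower. It called 1219 without STOX1B DMSO replicate 1 and 1170 without replicate 3.

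**Figure D2:**
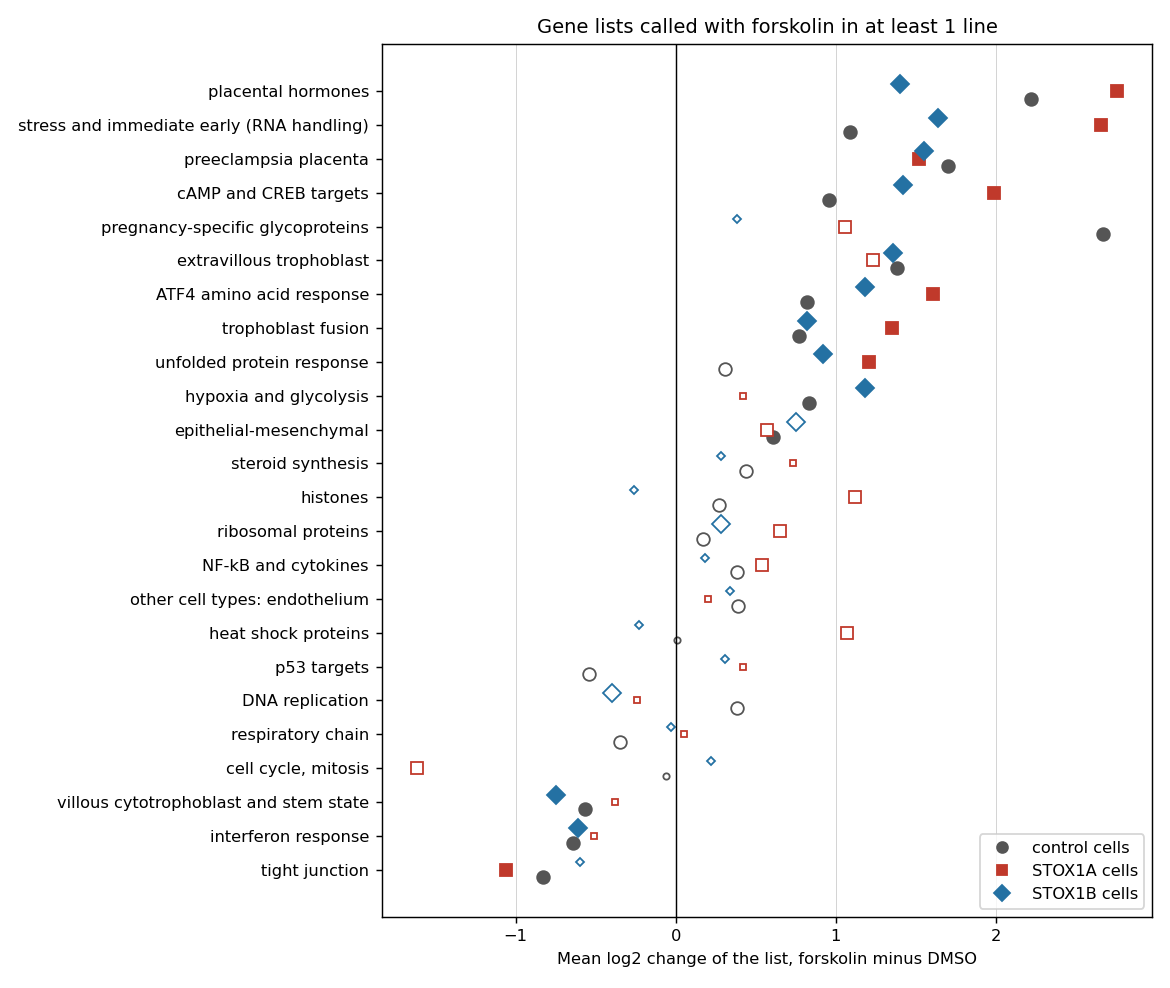
Mean log2 change of each gene list with forskolin (x axis) in control (grey circles), STOX1A (red squares) and STOX1B cells (blue diamonds); large symbols passed camera, filled ones also with an estimated correlation, and small ones did not pass. The placental hormone list had means of 2.22, 2.76 and 1.40 in control, STOX1A and STOX1B cells, with 13, 13 and 6 of its 27 genes called higher, and the mitosis list, with a mean of -1.62 in STOX1A cells, passed camera there but not with an estimated correlation.

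Between the lines, 167 rows were called higher with forskolin and 208 lower in all 3, and 77 were called in opposite directions in at least 1 pair of lines. HTRA4, MMP2, NR4A3, CGA, HEY1, SAT1, LAIR2, DDIT4 and ADM were among the rows called higher in all 3 lines, with CKMT1A, whose probes cannot be separated from those of its near-identical copy. IFI6, FADS2, LAMA1, LAMB1, FERMT1, FUT8, ARHGAP8, IFITM3 and the steroid sulfatase gene STS, with ANXA8L1, were among those called lower in all 3. DDIT4, a hypoxia- and stress-induced gene, rose by 4.96 ± 0.37 in control cells and from background by at least 5.60 in STOX1A and at least 5.04 in STOX1B cells. LAMB1 changed by -3.70 ± 0.39, -3.96 ± 0.32 and -3.92 ± 0.36 in the same order. Control and STOX1A cells shared 492 calls of 1 direction, against 30.1 higher and 57.5 lower for independent lists. STOX1A and STOX1B cells shared 1336, against 74.6 and 188.1, and control and STOX1B cells 438, against 14.5 and 21.5. These comparisons have no arrays in common.

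STOX1A cells under DMSO had lower p53 targets than control cells and differed in neighbouring genes of chromosome 21. FABP7, a fatty acid binding protein (at least 4.88), NMNAT2, an NAD synthesis enzyme (at least 5.17), aminopeptidase A (ENPEP, at least 4.02), cathepsin V (CTSV, 5.13 ± 0.33) and the basement membrane gene NID1 (4.12 ± 0.36) were higher. PRKACB, a catalytic subunit of protein kinase A (3.89 ± 0.38), the transporter gene ABCG2 (3.84 ± 0.24), DMKN (at least 1.48), PRKAA2 (at least 2.25) and CCR7 (3.58 ± 0.53) were higher too. FSTL3, a binder of activins (-5.68 ± 0.38), CAPN6 (at least 2.51 lower), BRWD1 (-5.32 ± 0.35), APOD (at least 3.23 lower) and keratin 7 (KRT7, -4.96 ± 0.31) were lower. GET1 (-4.78 ± 0.31), the side-chain cleavage enzyme CYP11A1 (-4.29 ± 0.52), the transferrin receptor (TFRC, -4.22 ± 0.34), MFSD12 (at least 2.66 lower) and P3H2 (at least 2.0 lower) were lower too. Adjusted p of these 20 genes were at most 0.00038.

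The p53 targets were lower in STOX1A cells under DMSO (13 of 25 lower, 14 lower and 1 higher adjusted over the list alone, mean -1.26, camera adjusted p = 1.7e-15, and adjusted p = 0.0092 with an estimated correlation). CDKN1A, a cell-cycle inhibitor, was at -3.97 ± 0.27, MDM2 at -3.37 ± 0.32, GDF15 at -2.82 ± 0.46 and PLK2 at -2.61 ± 0.33. The remaining lists of STOX1A against control under DMSO passed camera but not with an estimated correlation. The mitosis list (adjusted p = 0.081, 17 of 36 higher, 25 higher adjusted over the list alone) was higher, with TOP2A at 2.22 ± 0.29 and DLGAP5 at 2.09 ± 0.33, and so was the matrix list (adjusted p = 0.34, 4 of 35 higher, 4 higher and 1 lower adjusted over the list alone). The ribosomal protein list (adjusted p = 0.18, 15 of 42 lower, 21 lower adjusted over the list alone) was lower, with RPS28 at -2.33 ± 0.36. The antioxidant list (adjusted p = 0.19, 11 of 42 lower, 14 lower and 2 higher adjusted over the list alone) and the immediate early list (adjusted p = 0.11, 6 of 23 lower, 6 lower and 1 higher adjusted over the list alone) were also lower. The cytotrophoblast list (adjusted p = 0.19, 6 of 26 lower and 1 higher, 8 lower and 2 higher adjusted over the list alone) was lower, with EGFR at -3.22 ± 0.53. So was the preeclampsia list (adjusted p = 0.32, 7 of 32 lower and 1 higher, the same adjusted over the list alone), with endoglin (ENG) at -3.63 ± 0.42. The hypoxia and glycolysis list (adjusted p = 0.32, 7 of 37 lower and 1 higher, 12 lower and 2 higher adjusted over the list alone) and the ATF4 target list (adjusted p = 0.48, 5 of 36 lower and 1 higher, 9 lower and 1 higher adjusted over the list alone) were lower too. The respiratory chain list (adjusted p = 0.69, 5 of 53 lower and 1 higher, 10 lower and 2 higher adjusted over the list alone) and the histone list (adjusted p = 0.55, 0 of 43 called, the same adjusted over the list alone) completed the lower ones. The total was 1053 called rows, 399 higher and 654 lower. The higher share was 37.9% as deposited and 47.0% after quantile normalization. The total was 493 with only these 5 arrays, 683 without STOX1A DMSO replicate 2, 253 without control DMSO replicate 1 and 356 without replicate 3.

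STOX1B cells under DMSO had lower CGA and p53 targets than control cells and differed in the same chromosome 21 genes. Both p53 results share 2 control arrays, so are not independent. Under forskolin the list was called in neither STOX1 line. NMNAT2 (at least 4.44), SEMA5A (at least 3.57), CCR7 (3.98 ± 0.58), PRKACB (3.75 ± 0.42) and FABP7 (at least 2.91) were higher. The lysosomal lipase gene LIPA (at least 2.95), PLAC1 (at least 1.36), CTSV (3.15 ± 0.37), SOBP (at least 0.91) and CHST11 (2.88 ± 0.36) were higher too. CGA changed by -6.56 ± 0.44 and was above background on 1 of 2 STOX1B arrays. CYP11A1 (-5.15 ± 0.57), BRWD1 (-5.12 ± 0.38), GET1 (-4.45 ± 0.33), FSTL3 (-4.09 ± 0.41) and PSMG1 (-3.73 ± 0.35) were lower. HMGN1 (-3.71 ± 0.29), CAPN6 (at least 2.41 lower), CYP19A1 (at least 2.01 lower, adjusted p = 0.014) and ANXA1 (at least 0.55 lower) were lower too. The other 19 of these genes had adjusted p of at most 0.00096. The CYP19A1 call was lost without STOX1B DMSO replicate 3 (adjusted p = 0.25) and without control DMSO replicate 1 or 3 (adjusted p = 0.14 for each).

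The p53 targets were lower in STOX1B cells under DMSO (4 of 25 lower, 8 lower adjusted over the list alone, mean -0.86, camera adjusted p = 1.8e-11, and adjusted p = 0.024 with an estimated correlation), with CDKN1A at -2.06 ± 0.29. The other lists of this comparison lost the call with an estimated correlation. The matrix list (adjusted p = 0.11, 4 of 35 higher, 9 higher adjusted over the list alone), with COL12A1 at 2.79 ± 0.37, which lies in a block of chromosome 6 genes higher in this line, and the adhesion list (adjusted p = 0.11, 0 of 41 called, 2 higher adjusted over the list alone) were higher. The immediate early list (adjusted p = 0.056, 1 of 23 lower, 4 lower adjusted over the list alone) was lower. The placental hormone list (adjusted p = 0.16, 3 of 27 lower, 4 lower adjusted over the list alone) and the DNA replication list (adjusted p = 0.22, 0 of 39 called, 2 lower adjusted over the list alone) were lower too. The preeclampsia list (adjusted p = 0.23, 4 of 32 lower, 6 lower adjusted over the list alone) and the ribosomal protein list (adjusted p = 0.23, 0 of 42 called, the same adjusted over the list alone) were also lower. The cholesterol synthesis list (adjusted p = 0.38, 1 of 20 lower, 2 lower adjusted over the list alone) was lower. So were the hypoxia and glycolysis list (adjusted p = 0.4, 1 of 37 lower and 1 higher, 3 lower and 1 higher adjusted over the list alone) and the ATF4 target list (adjusted p = 0.4, 1 of 36 lower, the same adjusted over the list alone). The fit called 195 rows, 109 higher and 86 lower, against 460 with array weights. It called 72 without STOX1B DMSO replicate 3, 59 without control DMSO replicate 1 and 64 without replicate 3.

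BRWD1, GET1, PSMG1, HMGN1 and ETS2 lie next to each other among the expressed genes of chromosome 21 and were lower in both STOX1 lines under both treatments. HMGN1, a nucleosome-binding protein, differed by -3.93 ± 0.26 in STOX1A and -3.71 ± 0.29 in STOX1B cells under DMSO, and by -3.77 ± 0.26 and -3.76 ± 0.26 under forskolin. ETS2 and HMGN1 in STOX1A cells were named here after their values were seen.

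**Figure D3:**
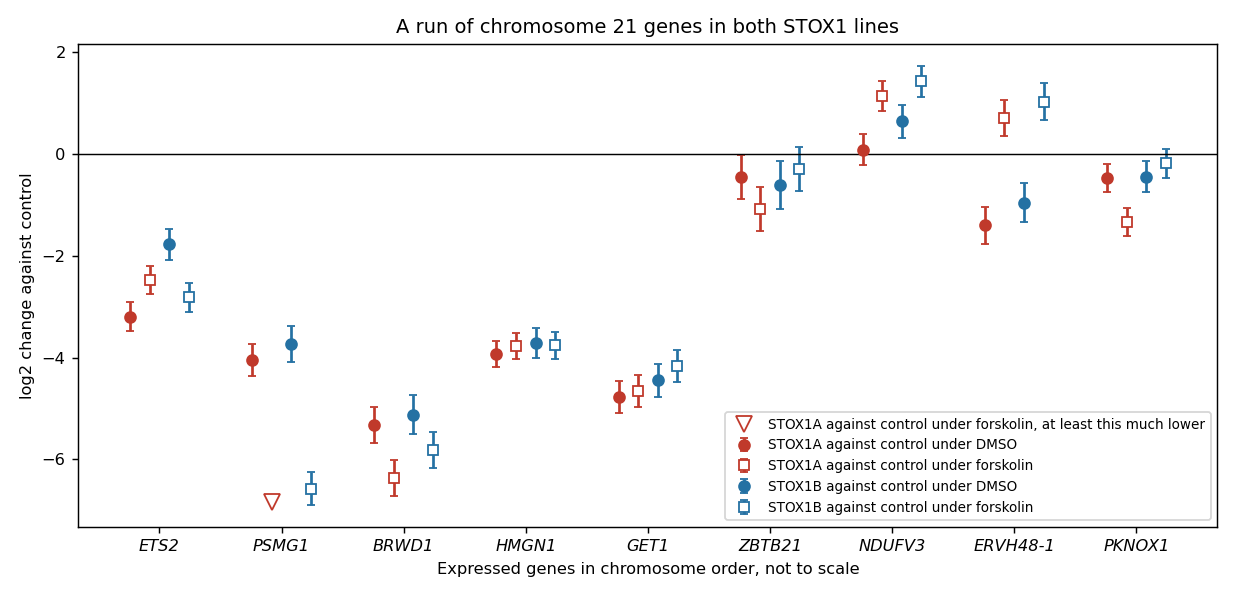
Difference from control in log2 signal (y axis, ± standard error of the fit) for 9 neighbouring expressed genes of chromosome 21 in their order (x axis, not to scale), in STOX1A (red) and STOX1B (blue) under DMSO (filled circles) and forskolin (open squares). The values of the first 5 genes, ETS2 to GET1, lie between -1.78 and -6.57, except PSMG1 in STOX1A cells under forskolin, which lay at background and is drawn as a triangle at its bound (at least 6.83 lower), and those of the other 4 lie between -1.41 and 1.42.

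Under DMSO, 121 rows were called in 1 direction in both STOX1 lines against control, and 3 in opposite directions, with 2.5 higher and 3.2 lower for independent lists. Both comparisons use the same 2 control arrays, so unchanged groups were simulated. With no row changed they shared 0 calls, which decides nothing. Their correlation of log2 changes across rows was 0.547 (0.542 observed) and covariance 0.0622 (0.1587 observed, difference 0.0965). Under forskolin 882 rows were shared and 63 were opposite, with 39.1 and 105.1 for independent lists. There the simulated values were 0.602 (0.568 observed) and 0.0628 (0.3393 observed, difference 0.2765). Rows are not independent replicates. With 1 control array given to each line, both ways, 35 and 34 rows were shared under DMSO, with correlations of 0.353 and 0.394. Under forskolin 291 and 366 were shared, with 0.478 and 0.514, so part of the excess may come from the shared controls. The 121 shared rows became 256 with array weights, 44 without STOX1B DMSO replicate 3, and 39 and 43 without control DMSO replicates 1 and 3. The 882 became 1600 with array weights, and 306 and 450 without control forskolin replicates 1 and 2.

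Under forskolin, STOX1A cells were higher than control cells in immediate early genes, among them the nuclear receptor genes NR4A1 and NR4A2. NR4A2 (at least 7.04), ALPG (7.93 ± 0.29), NR4A1 (7.40 ± 0.33), CCR7 (6.65 ± 0.53) and ACKR3 (at least 5.30) were higher. LRRC15 (at least 4.96), ATP1B3 (5.60 ± 0.32), PGC (at least 4.15), RFLNB (5.28 ± 0.30) and STAG2 (5.27 ± 0.35) were higher too. TNFSF10 (-10.34 ± 0.56), FAM83D (-7.81 ± 0.76), PSMG1 (at least 6.83 lower), CAPN6 (at least 3.78 lower) and caveolin-1 (CAV1, -6.50 ± 0.34) were lower. BRWD1 (-6.37 ± 0.35), TFRC (-6.28 ± 0.34), TRAM2 (-6.12 ± 0.38), GPR32 (-6.11 ± 0.55) and KRT7 (-6.00 ± 0.31) were lower as well (adjusted p of these 20 at or below 9.4e-07).

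Immediate early genes were higher in STOX1A than in control cells under forskolin (12 of 23 higher, the same adjusted over the list alone, mean 1.10, camera adjusted p = 5.4e-06, and adjusted p = 0.025 with an estimated correlation). The lists that follow lost the call with an estimated correlation. The heat shock list (adjusted p = 0.24, 8 of 20 higher, 9 higher adjusted over the list alone), with HSPA1A at 4.11 ± 0.45, and the unfolded protein response list (adjusted p = 0.24, 10 of 33 higher and 1 lower, the same adjusted over the list alone), with PDIA3 at 2.27 ± 0.29, were higher. The cAMP and CREB target list (adjusted p = 0.24, 8 of 30 higher and 2 lower, 10 higher and 3 lower adjusted over the list alone) and the trophoblast fusion list (adjusted p = 0.24, 9 of 24 higher and 3 lower, the same adjusted over the list alone) were also higher. So were the matrix list (adjusted p = 0.24, 8 of 35 higher, 9 higher adjusted over the list alone) and the histone list (adjusted p = 0.32, 13 of 43 higher and 2 lower, 14 higher and 2 lower adjusted over the list alone). The pregnancy-specific glycoprotein list (adjusted p = 0.13, 8 of 10 lower, the same adjusted over the list alone), with PSG9 at least 2.06 lower, and the DNA replication list (adjusted p = 0.24, 18 of 39 lower, the same adjusted over the list alone), with MCM7 at -2.76 ± 0.42, were lower. The hypoxia and glycolysis list (adjusted p = 0.24, 15 of 37 lower and 1 higher, 16 lower and 1 higher adjusted over the list alone), with the glucose transporter gene SLC2A1 at -5.26 ± 0.65, and the preeclampsia list (adjusted p = 0.41, 10 of 32 lower and 3 higher, the same adjusted over the list alone) were lower as well. So were the mitosis list (adjusted p = 0.54, 11 of 36 lower and 5 higher, 11 lower and 6 higher adjusted over the list alone) and the ribosomal protein list (adjusted p = 0.65, 7 of 42 lower, the same adjusted over the list alone). Of 3234 called rows, 1055 were higher and 2179 lower. The higher share was 32.6%, and 46.7% after quantile normalization. The number was 1580 without control forskolin replicate 1 and 1954 without replicate 2.

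STOX1B cells under forskolin were lower than control cells in placental hormone, pregnancy-specific glycoprotein and DNA replication genes. CGB8 (-6.23 ± 0.50), CGB3 (at least 5.09 lower), CGB5 (at least 5.35 lower), CGB1 (at least 3.63 lower) and CYP19A1 (at least 3.62 lower) were lower. The heme oxygenase gene HMOX1 (-5.15 ± 0.39), AGPAT5 (at least 4.37 lower), CAPN6 (at least 4.04 lower), PSMG1 (-6.57 ± 0.32) and BRWD1 (-5.81 ± 0.35) were lower too. OLR1 (9.32 ± 0.53), CCN1 (7.15 ± 0.46), RFLNB (5.81 ± 0.30), ATP1B3 (5.30 ± 0.32) and SEMA5A (at least 3.24) were higher. Cystathionine gamma-lyase (CTH, at least 4.15), NR4A2 (at least 2.79), SOBP (at least 2.11), EMILIN2 (at least 3.21) and PTP4A1 (3.95 ± 0.23) were higher too, all 20 with adjusted p at or below 6.6e-05. PTP4A1 lies in the block of chromosome 6 genes that was higher in this line.

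Pregnancy-specific glycoproteins were lower in STOX1B than in control cells under forskolin (9 of 10 lower, the same adjusted over the list alone, mean -2.45), and so were placental hormones (10 of 27 lower, 11 lower adjusted over the list alone, mean -1.5). DNA replication genes were lower (21 of 39 lower, 25 lower adjusted over the list alone, mean -1.22), with MCM7 at least 2.59 lower, RRM2 at -3.55 ± 0.33 and CCNE1 at -3.20 ± 0.40. These 3 lists kept their calls with an estimated correlation (adjusted p = 0.0064, 0.017 and 0.017). Lost with an estimated correlation were the unfolded protein response list (adjusted p = 0.075, 12 of 33 higher, 15 higher and 1 lower adjusted over the list alone) and the matrix list (adjusted p = 0.075, 8 of 35 higher, 10 higher adjusted over the list alone), both higher. The histone list (adjusted p = 0.18, 8 of 43 lower, 14 lower adjusted over the list alone) and the preeclampsia list (adjusted p = 0.29, 8 of 32 lower and 1 higher, 9 lower and 2 higher adjusted over the list alone), both lower, were lost too. The heat shock list (adjusted p = 0.56, 5 of 20 lower and 1 higher, 8 lower and 3 higher adjusted over the list alone) and the ribosomal protein list (adjusted p = 0.56, 1 of 42 lower, the same adjusted over the list alone) were likewise lower. The mitosis list (adjusted p = 0.73, 6 of 36 higher and 1 lower, 8 higher and 2 lower adjusted over the list alone) and the respiratory chain list (adjusted p = 0.73, 5 of 53 higher, the same adjusted over the list alone), both higher, were the remaining ones lost. The fit called 1511 rows, 657 higher and 854 lower. It called 2894 with array weights, 2311 with only these 5 arrays, 583 without control forskolin replicate 1 and 784 without replicate 2.

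Comparing the isoforms under DMSO, CGA was 6.55 ± 0.40 higher in STOX1A cells, and so were PRKAA2 (at least 1.86), ABCG2 (4.21 ± 0.24), DMKN (at least 1.08) and ENPEP (3.57 ± 0.43). APOD (at least 4.96 lower), OLR1 (-4.23 ± 0.53) and the metallothionein rows MT1E (-5.04 ± 0.35), MT2A (-4.18 ± 0.48) and MT1L (-3.63 ± 0.39), which share sequence with each other, were lower in STOX1A than in STOX1B cells. The 9 lists called by camera here were all lost with an estimated correlation. The mitosis list (adjusted p = 0.073, 15 of 36 higher, 25 higher adjusted over the list alone) was higher in STOX1A cells, with a mean of 1.02, and so was the DNA replication list (adjusted p = 0.74, 2 of 39 higher and 1 lower, 6 higher and 1 lower adjusted over the list alone). The adhesion list (adjusted p = 0.073, 5 of 41 lower, the same adjusted over the list alone), with ITGA5 at -1.81 ± 0.27, and the p53 target list (adjusted p = 0.34, 5 of 25 lower, 6 lower and 1 higher adjusted over the list alone), with CDKN1A at -1.91 ± 0.27, were lower. The cytotrophoblast list (adjusted p = 0.28, 3 of 26 lower, 5 lower adjusted over the list alone) was lower too. The antioxidant list (adjusted p = 0.38, 2 of 42 lower, 9 lower adjusted over the list alone) and the unfolded protein response list (adjusted p = 0.38, 2 of 33 lower, 6 lower adjusted over the list alone) were also lower. So were the ribosomal protein list (adjusted p = 0.74, 3 of 42 lower, 5 lower adjusted over the list alone) and the respiratory chain list (adjusted p = 0.81, 2 of 53 lower, 4 lower and 2 higher adjusted over the list alone). Of 539 called rows, 222 were higher and 317 lower. The number was 92 with only these 5 arrays, 311 without STOX1A DMSO replicate 2, 859 without replicate 3, 244 without STOX1B DMSO replicate 1 and 179 without replicate 3.

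Under forskolin the isoforms differed in the beta subunit rows, with CGB8 8.53 ± 0.45, CGB5 at least 7.73, CGB3 at least 7.35 and CGB1 at least 5.82 higher in STOX1A cells. The amino acid transporter gene SLC7A8 was at least 6.53 higher. OLR1 (-8.10 ± 0.47), TNFSF10 (-6.79 ± 0.51), PLAC8 (-5.96 ± 0.31), the natriuretic peptide gene NPPB (at least 3.20 lower) and APOD (at least 2.40 lower) were lower. Immediate early genes were higher in STOX1A than in STOX1B cells (12 of 23 higher and 1 lower, the same adjusted over the list alone, adjusted p = 0.011 with an estimated correlation), with ATF3 at 2.97 ± 0.24. The other lists of the isoforms under forskolin lost the call with an estimated correlation. The histone list (adjusted p = 0.054, 26 of 43 higher, 28 higher and 1 lower adjusted over the list alone) was higher, with H2BC12 at 3.75 ± 0.32. The heat shock list (adjusted p = 0.1, 11 of 20 higher and 2 lower, 13 higher and 2 lower adjusted over the list alone) was higher, with HSPA1A at 5.79 ± 0.40. So was the cAMP and CREB target list (adjusted p = 0.17, 8 of 30 higher and 3 lower, 8 higher and 5 lower adjusted over the list alone), with RGS2 at 4.68 ± 0.41. The placental hormone list (adjusted p = 0.058, 8 of 27 higher and 2 lower, the same adjusted over the list alone) was higher too. The pregnancy-specific glycoprotein list (adjusted p = 0.13, 3 of 10 higher, the same adjusted over the list alone) and the NF-kB and cytokine list (adjusted p = 0.13, 3 of 27 higher, 2 higher adjusted over the list alone) were also higher. So were the DNA replication list (adjusted p = 0.42, 7 of 39 higher and 3 lower, 10 higher and 4 lower adjusted over the list alone) and the ATF4 target list (adjusted p = 0.4, 9 of 36 higher and 3 lower, 10 higher and 4 lower adjusted over the list alone). The mitosis list (adjusted p = 0.18, 15 of 36 lower and 1 higher, 18 lower and 1 higher adjusted over the list alone) was lower, with PLK1 at -2.48 ± 0.28. The hypoxia and glycolysis list (adjusted p = 0.14, 14 of 37 lower and 1 higher, 18 lower and 3 higher adjusted over the list alone) was lower, with HK2 at -2.93 ± 0.40. The fit called 2671 rows, 895 higher and 1776 lower, with 33.5% higher as deposited and 45.9% after quantile normalization.

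The forskolin response itself differed between STOX1A and control cells in 1387 rows, 481 with a more positive and 906 with a more negative change in STOX1A cells. ALPG (8.12 ± 0.41) and the stress regulator gene NUPR1 (6.13 ± 0.68) changed more positively in STOX1A cells. NR4A2 (adjusted p = 8.3e-08), NR4A1 (adjusted p = 2.5e-08) and LRRC15 (adjusted p = 8.3e-08) passed the test without a size or direction, because control arrays lay below background. TNFSF10 (-6.34 ± 0.80), FAM83D (-6.01 ± 1.08), VTCN1 (at least 3.64 lower), the tropomyosin gene TPM1 (-4.91 ± 0.49) and CENPF (at least 3.76 lower) changed more negatively. ERVFRD-1 was called with a difference of at least 2.54 and HSD11B2 without a size or direction (adjusted p = 0.00086), and CGA, CGB3, ERVW-1, GCM1, CYP19A1, CDH1 and GJA1 were not. For these differences, higher means a more positive change. Immediate early genes changed more positively in STOX1A cells (10 of 23 higher, 13 higher adjusted over the list alone, mean 1.57, adjusted p = 0.0033 with an estimated correlation). The lists named next lost the call with an estimated correlation. The mitosis list (adjusted p = 0.071, 20 of 36 lower, 21 lower adjusted over the list alone) was lower, with a mean of -1.56. The pregnancy-specific glycoprotein list (adjusted p = 0.071, 4 of 10 lower, 6 lower adjusted over the list alone) and the DNA replication list (adjusted p = 0.28, 7 of 39 lower, 10 lower and 1 higher adjusted over the list alone) were also lower. The p53 target list (adjusted p = 0.071, 7 of 25 higher, 9 higher and 1 lower adjusted over the list alone), with GADD45A at 3.38 ± 0.42, and the cAMP and CREB target list (adjusted p = 0.071, 7 of 30 higher and 3 lower, 10 higher and 4 lower adjusted over the list alone) were higher. So were the unfolded protein response list (adjusted p = 0.075, 10 of 33 higher, 13 higher and 1 lower adjusted over the list alone), the histone list (adjusted p = 0.17, 11 of 43 higher, 15 higher adjusted over the list alone) and the ATF4 target list (adjusted p = 0.24, 8 of 36 higher and 1 lower, 10 higher and 1 lower adjusted over the list alone). The heat shock list (adjusted p = 0.28, 4 of 20 higher, 5 higher and 1 lower adjusted over the list alone) was higher too. So were the ribosomal protein list (adjusted p = 0.47, 2 of 42 higher, 0 adjusted over the list alone) and the respiratory chain list (adjusted p = 0.65, 1 of 53 higher and 1 lower, the same adjusted over the list alone). The share of positive differences was 34.7%, and 45.9% after quantile normalization. The count was 641 without control DMSO replicate 1 and 644 without control forskolin replicate 1.

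Between STOX1B and control cells the response differed in 209 rows, 108 positive and 101 negative. CCN1 (7.66 ± 0.68), OLR1 (6.49 ± 0.79), NPPB (at least 5.15) and ATP1B3 (4.98 ± 0.47) changed more positively in STOX1B cells, and the oncogene MYCN more negatively (-5.19 ± 0.58). CGB8, CGB3, CGB5 and CGB1 passed the test (adjusted p = 0.00037, 0.0015, 0.00034 and 0.0051) without a size or direction, because STOX1B arrays lay below background. CGA passed it too (adjusted p = 1.6e-05), but it had reached the top of the scale under forskolin in both lines, so neither size nor direction can be read. Pregnancy-specific glycoproteins changed less positively in STOX1B cells (5 of 10 lower, 8 lower adjusted over the list alone, mean -2.29, adjusted p = 0.0065 with an estimated correlation). The p53 targets changed more positively (4 of 25 higher, 6 higher adjusted over the list alone, mean 0.85), with CDKN1A at 1.97 ± 0.40, and adjusted p = 0.05 with an estimated correlation, which before rounding lies under the threshold. The next lists lost the call with an estimated correlation. The DNA replication list (adjusted p = 0.12, 3 of 39 lower, 5 lower adjusted over the list alone) and the histone list (adjusted p = 0.34, 0 of 43 called, 5 lower adjusted over the list alone) were lower. The immediate early list (adjusted p = 0.12, 2 of 23 higher, 4 higher adjusted over the list alone) was higher. The unfolded protein response list (adjusted p = 0.13, 2 of 33 higher, 7 higher and 1 lower adjusted over the list alone) and the cAMP and CREB target list (adjusted p = 0.31, 4 of 30 higher and 1 lower, 6 higher and 1 lower adjusted over the list alone) were higher too. So were the hypoxia and glycolysis list (adjusted p = 0.51, 2 of 37 higher and 1 lower, 4 higher and 1 lower adjusted over the list alone) and the respiratory chain list (adjusted p = 0.81, 0 of 53 called, the same adjusted over the list alone). The placental hormone list (adjusted p = 0.23, 6 of 27 lower and 1 higher, 9 lower and 3 higher adjusted over the list alone) was lower by its mean of -0.82 and by camera, but its median was 0.03. The count was 618 with array weights and 522 with only these 9 arrays. It was 132 and 110 without STOX1B DMSO replicates 1 and 3, 76 and 85 without control DMSO replicates 1 and 3, and 83 and 110 without control forskolin replicates 1 and 2. CGB1 lost its call without control DMSO replicate 3 (adjusted p = 0.053). CDKN1A lost it without STOX1B DMSO replicates 1 and 3 (adjusted p = 0.071 and 0.057), control DMSO replicates 1 and 3 (adjusted p = 0.065 and 0.10) and control forskolin replicate 1 (adjusted p = 0.14).

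Between the isoforms the response differed in 1140 rows, 378 positive for STOX1A and 762 negative. SLC7A8 changed more positively in STOX1A cells by at least 6.31. CGB3, CGB5, CGB8 and CGB1 passed the test (adjusted p = 2.3e-05, 4.2e-06, 9.7e-06 and 0.00011) without a size or direction, because STOX1B arrays lay below background. So did CGA (adjusted p = 1.4e-06), because of the top of the scale. NPPB (at least 2.74 lower), TNFSF10 (-4.90 ± 0.76) and the near-identical rows FAM72B (-5.60 ± 0.62) and FAM72D (-4.99 ± 0.52) changed more negatively. Of the genes fixed in advance, ERVW-1 (1.96 ± 0.45, adjusted p = 0.011) was also called, and so were ERVFRD-1 and HSD11B2 without a size or direction (adjusted p = 0.00024 and 0.00054). Mitosis genes changed more negatively in STOX1A cells (24 of 36 lower, 28 lower adjusted over the list alone, mean -1.83, adjusted p = 0.036 with an estimated correlation). Histones (19 of 43 higher, 25 higher adjusted over the list alone, mean 1.38, adjusted p = 0.038 with an estimated correlation) and immediate early genes (8 of 23 higher, 10 higher and 1 lower adjusted over the list alone, mean 1.02, adjusted p = 0.020 with an estimated correlation) changed more positively. The following lists lost the call with an estimated correlation. The placental hormone list (adjusted p = 0.11, 8 of 27 higher and 1 lower, 8 higher and 3 lower adjusted over the list alone) was higher. The heat shock list (adjusted p = 0.13, 6 of 20 higher, the same adjusted over the list alone) and the NF-kB and cytokine list (adjusted p = 0.13, 1 of 27 higher, the same adjusted over the list alone) were higher too. The cAMP and CREB target list (adjusted p = 0.25, 7 of 30 higher and 3 lower, the same adjusted over the list alone) was also higher. So were the pregnancy-specific glycoprotein list (adjusted p = 0.29, 0 of 10 called, 2 higher adjusted over the list alone) and the ATF4 target list (adjusted p = 0.41, 4 of 36 higher and 2 lower, 6 higher and 4 lower adjusted over the list alone). The antioxidant list (adjusted p = 0.41, 3 of 42 higher, 6 higher adjusted over the list alone) and the ribosomal protein list (adjusted p = 0.51, 1 of 42 higher, 0 adjusted over the list alone) were higher as well. The hypoxia and glycolysis list (adjusted p = 0.3, 9 of 37 lower, 10 lower and 1 higher adjusted over the list alone) was lower. The positive share was 33.2%, and 47.4% after quantile normalization, and the count was 695 without STOX1B DMSO replicate 3.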

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

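The tests of a mislabelled array and of the top of the scale were chosen only after the result was seen. Groups of 2 or 3 arrays are too small for an outlier test, so the results here were picked out because the forskolin effect differed between lines by the interaction test. Where rows at background or at the top of the scale allow neither size nor direction, the adjusted p alone is given. In STOX1A against control cells these were ALPG (8.12 ± 0.41), NUPR1 (6.13 ± 0.68), ERVFRD-1 (at least 2.54), NR4A2 (adjusted p = 8.3e-08), NR4A1 (adjusted p = 2.5e-08), LRRC15 (adjusted p = 8.3e-08), HSD11B2 (adjusted p = 0.00086), TNFSF10 (-6.34 ± 0.80), FAM83D (-6.01 ± 1.08), VTCN1 (at least 3.64 lower), TPM1 (-4.91 ± 0.49), CENPF (at least 3.76 lower) and the immediate early list (mean 1.57). In STOX1B against control cells they were CCN1 (7.66 ± 0.68), OLR1 (6.49 ± 0.79), NPPB (at least 5.15), ATP1B3 (4.98 ± 0.47), CGA (adjusted p = 1.6e-05), CGB8 (adjusted p = 0.00037), CGB3 (adjusted p = 0.0015), CGB5 (adjusted p = 0.00034), CGB1 (adjusted p = 0.0051), MYCN (-5.19 ± 0.58) and the pregnancy-specific glycoproteins (mean -2.29). In STOX1A against STOX1B cells they were SLC7A8 (at least 6.31), ERVW-1 (1.96 ± 0.45), CGB3 (adjusted p = 2.3e-05), CGB5 (adjusted p = 4.2e-06), CGB8 (adjusted p = 9.7e-06), CGB1 (adjusted p = 0.00011), ERVFRD-1 (adjusted p = 0.00024), HSD11B2 (adjusted p = 0.00054), CGA (adjusted p = 1.4e-06), FAM72B (-5.60 ± 0.62), NPPB (at least 2.74 lower), FAM72D (-4.99 ± 0.52), TNFSF10 (-4.90 ± 0.76), mitosis genes (mean -1.83), histones (mean 1.38) and immediate early genes (mean 1.02).

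Forskolin called 4641 rows in STOX1A cells and 663 in control cells, 3411 and 1621 with only the groups compared, and 3955 and 1858 with array weights. With all groups fitted, array number does not explain it, since 9 choices of 2 against 2 STOX1A arrays each called at least 3528. With only the groups compared it was not tested. Quantile normalization (4475 against 651 rows) restores no signal lost in background, so a narrower STOX1A forskolin range stays open. The spread of true effects was 1.97 times as wide in STOX1A as in control cells, but this restates the counts. Its 95% interval (1.88 to 2.06) covers rows, not arrays. STOX1A expression and other line differences also stay open, untested, as the labels do not say how many clones or transfections a line had.

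In STOX1B cells CGA rose with forskolin and the CGB rows did not. A failure of forskolin to act is argued against, since 74.2% of the 225 rows raised in both other lines were called higher there. CGB5 lay below the lowest other forskolin array by at least 5.02 log2 units on 3 of the 3 STOX1B arrays, which a single wrong label cannot give, though a mix-up of the whole group is not excluded by this. CGA lay within 0.3 log2 units of the brightest row on 8 of 8 forskolin arrays, so its end levels cannot be ranked between lines, and this bears on CGA alone. The STOX1B construct and other differences of that line stay open, as untested.

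For groups of 3 against 3 arrays, 10 splits are too few for a share under 0.05. The real split (1 of 10) called 4641 rows for forskolin in STOX1A cells and 2671 for STOX1A against STOX1B under forskolin. The others called at most 0.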

How the results depend on the processing

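Among the alternatives here, the background filter, the removal of regional blocks and the split of the control arrays were chosen after seeing the data, and no count moved by over 1.5 times with the first 2. The split, which leaves 1 control array per line, lowered the shared calls of both STOX1 lines to 35 and 34 under DMSO and to 291 and 366 under forskolin. Array weights, which gave the control arrays the most weight, raised forskolin in control cells from 663 to 1858, STOX1B against control from 195 to 460 under DMSO and from 1511 to 2894 under forskolin, the difference of their forskolin effects from 209 to 618, and the shared calls of both STOX1 lines from 121 to 256 under DMSO and from 882 to 1600 under forskolin. With only the groups compared, the counts were 1621 for forskolin in control cells, 2311 for STOX1B against control under forskolin, 522 for the difference of their forskolin effects, 493 for STOX1A against control under DMSO and 92 for STOX1A against STOX1B under DMSO. These fits have fewer arrays to estimate the spread. Passing list tests fell from 153 to 45 with an estimated correlation, and ribosomal proteins turned from a mean of 0.17 to -0.13 in control and from 0.28 to -0.17 in STOX1B cells with quantile normalization; the cause was not tested.

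Leaving out 1 array (a group left with 1 array is then assumed to vary like the others) gave 359 to 740 rows for forskolin in control, 3879 to 4640 in STOX1A and 1170 to 2107 in STOX1B cells. The ranges were 253 to 1378 and 59 to 262 for STOX1A and STOX1B against control under DMSO, 1580 to 3456 and 583 to 1682 under forskolin, 179 to 859 and 2044 to 2906 for STOX1A against STOX1B under DMSO and forskolin, and 641 to 1544, 76 to 268 and 695 to 1317 for the differences of forskolin effects (STOX1A and control, STOX1B and control, STOX1A and STOX1B). The shared calls ranged from 39 to 150 and from 306 to 988, and the list tests from 145 to 159. Fewer arrays in the smaller groups lower the counts by construction.

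Of 635 named results of single genes, of which 603 were tested without the regional blocks, 620 with the background filter and 634 without the dimmest rows, none changed direction in the alternatives it was tested in. Of them 124 lost their call without at least 1 array, 45 with only the groups compared, 31 with the replicate block, 24 with quantile normalization, 14 with array weights, 6 with the trended prior and 3 each with medians subtracted, without the dimmest rows and without the regional blocks. Of the 153 list results, 45 lost it without at least 1 array, 38 with fry, 20 of 152 tested with the background filter, 17 with quantile normalization, 12 with the replicate block, 11 without the dimmest rows and 4 without the regional blocks. All of these are among the 108 lost with an estimated correlation, except 1 lost with the background filter (tight junction genes with forskolin in STOX1A cells, adjusted p = 0.11).

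The replicate numbers did not pair the arrays: 29 correlations of same-numbered arrays ran from -0.205 to 0.213, 3 of them above 0.1 and 4 below -0.1. With the replicate block the counts were 541, 4524 and 1669 for forskolin in control, STOX1A and STOX1B cells, 835 and 163 for the STOX1 lines against control under DMSO, 3062 and 1454 under forskolin, 378 and 2520 for STOX1A against STOX1B, and 1159, 159 and 955 for the differences of forskolin effects, none moved by over 1.5 times. Signal over background limits the remainder: 26.0% to 39.6% of rows exceeded it, and rows at background give only bounds.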

Other observations

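The grouping of the metallothionein rows and the tests on 9 chromosome 21 genes and on the chromosome 21 run of the STOX1A line were chosen only after the result was seen. The metallothionein genes, which bind zinc and copper, were lower in STOX1A cells than in both other lines under DMSO. Of 10 rows, 9 were called lower against control, with changes from -4.10 (MT2A) to -2.11 (MT1F). The same 9 were called lower against STOX1B cells, from -5.04 (MT1E) to -2.0 (MT1M). MT1IP, below background in the 3 lines, was the row not called (adjusted p = 0.18 and 0.22). Between STOX1B and control cells limma called 0 of the 10 (-0.51 to 1.10), and 1 had an unadjusted p under 0.05 (MT1E, 1.10 ± 0.38). Under forskolin 1 of the 10 was called between the isoforms (MT1E, -1.88 ± 0.31). APOD, a lipocalin, was lower in STOX1A (at least 3.23) and higher in STOX1B cells (1.73 ± 0.31, adjusted p = 0.0061) than in control cells.

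The markers of other cell types gave no call for fibroblasts and stroma (lowest camera adjusted p of the 12 comparisons 0.39), neurons and glia (0.27) or blood and macrophages (0.076), and neither did TGF-beta and BMP targets (0.053), the Wnt pathway (0.66) or imprinted genes (0.075).

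Genes were also ordered along the chromosomes (5837 expressed genes, windows of 8), and window medians that moved in 1 direction under both treatments were set against the 95th percentile of the largest one in each of 1000 shuffles of the gene order (1.3 for STOX1A and 0.92 for STOX1B against control, 1.11 between the isoforms). STOX1B differed from control over 13 genes of chromosome 5 from PJA2 to AP3S1 (median 0.81 under DMSO and 1.22 under forskolin, 13 of 13 higher under each), over 36 genes of chromosome 6 from RAB23 to MAP3K7 (1.13 and 1.08, 31 and 29 higher), a block that includes CGA by position although CGA was lower under DMSO, and over 28 genes of chromosome 19 from ZNF836 to NLRP2 (-0.97 and -1.49, 26 and 25 lower). In STOX1A against the same control arrays, the chromosome 5 genes had medians of 0.90 and 0.60 (13 and 9 of 13 above 0), the chromosome 19 genes of -0.60 and -1.84 (28 and 25 of 28 below 0) and the chromosome 6 genes of 0.23 and -0.26, so the blocks of chromosomes 5 and 19 are not shown to be particular to STOX1B. Between the isoforms, 11 genes of chromosome 5 from CLTB to RMND5B were lower in STOX1A cells (-1.10 and -1.14, 11 of 11 under each), and so were 2 stretches inside the chromosome 6 block, SMAP1 to SENP6 (10 genes, -1.11 and -1.55, 8 and 9 lower) and RARS2 to MAP3K7 (8 genes, -1.11 and -1.95, 8 of 8 lower under each). The largest window median between the isoforms (-1.21) did not exceed the largest shuffled one (1.46).

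On chromosome 21, ETS2, PSMG1, BRWD1, HMGN1 and GET1 were lower in both STOX1 lines under both treatments, and the largest window medians were -3.13 in STOX1A and -2.75 in STOX1B against control, beyond the largest shuffled ones (1.79 and 1.24). For the 9 genes common to the runs of both lines, a change in 1 control array is argued against, since their median stayed at -1.36 or lower in the 4 comparisons without any 1 of the 4 control arrays. The longer run of STOX1A (13 genes) does not decide this, since its weakest median was -0.48 both with all arrays and without 1. A copy-number difference between the lines may be the reason, but stays open. The share of genes below 0, asked beforehand to be over 80% and to argue against it under 60%, depends on the run's end. It was 61.5% at the lowest in a line's own run (STOX1A under forskolin, 13 genes). Those genes gave 53.8% in STOX1B under forskolin, 4 of them outside its run. The 9 common genes had 8 below 0 under DMSO and 7 (77.8%) under forskolin in each line. No biological explanation was tested, and the arrays hold no measure of DNA.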
